A study of Bos taurus with 20 samples.

How the data were processed

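RNA from 2 areas of the bovine endometrium was compared on 2-colour oligonucleotide arrays. Caruncles are the raised, gland-free areas where the placenta attaches in ruminants, and the intercaruncular endometrium between them holds the uterine glands. Each array carried caruncular RNA in 1 dye and intercaruncular RNA from the same cow in the other, and each cow was measured on 2 arrays with the dyes exchanged, per the labels. The 20 arrays therefore came from 10 cows, 5 cyclic and 5 pregnant, and the cow was the replicate (n = 5 per group). The 2 arrays of a cow were technical repeats. Slide numbers ran through the cyclic cows and then the pregnant cows, so slide order and state could not be separated.

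The deposited table holds 1 log ratio per spot and array, read here as log2. The log base, the normalisation, the background correction, any centring and the direction of the ratio are not given in the sources used here. The log base was taken as 2. All arrays had values on both sides of 0 and medians near 0. With caruncle in Cy3 the medians of cyclic cows 1 to 5 were -0.0058, -0.00030, -0.0052, -0.00030 and -0.0065, and with caruncle in Cy5 they were -0.00010, -0.0017, 0, -0.010 and 0.0038. In pregnant cows 1 to 5 they were 0.0030, -0.0043, 0.0014, -0.0059 and -0.0032 with caruncle in Cy3, and 0.0013, 0.0033, 0.0046, 0.019 and -0.016 with caruncle in Cy5. Values centred on such medians show each gene relative to the other genes of the array.

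The direction of each array was examined through the correlation of the 2 dye-swapped arrays of each cow. In cyclic cows these correlations were 0.668, 0.591, 0.450, 0.262 and 0.0399, so the table was taken as already turned to 1 order of tissues and no sign was changed. In pregnant cows they were -0.0844, -0.0664, 0.183, -0.114 and -0.216, which leaves the direction of some arrays unsettled. The array of pregnant cow 1 with caruncle in Cy3 correlated below 0 with 17 of the 19 other arrays, and below -0.3 with 4 of them. Values are given as deposited, and the text gives results with arrays turned or left out for the counts, for list calls that they end and for several named genes of pregnant cows. Positive values are read as higher in caruncle, which is likely but not stated by any source. That reading rests on the Cy5 over Cy3 ratio of the arrays with caruncle in Cy5 and on the order in which the series names the tissues. A fixed list of uterine gland products was meant to settle it and did not (6 genes above 0 and 6 below). The sign of every list, the epithelial one included, depends on this reading, and all signs turn together if it is wrong.

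The table held 27648 spots, which formed 13824 features of 2 spots each. Spots of a feature were averaged on each array, and the 2 arrays of a cow were averaged. A feature needed a value in at least 3 cows of each group, which kept 13821. Of all features, 8645 had 1 gene symbol, 105 had several and 5074 had none. Symbols were looked up in a RefSeq table without changing any, and no genome came with the data, so no positions are given. The 8645 features covered 8073 genes, of which 518 had more than 1 feature, and a gene value was the mean of its features. Missing spots per array ranged from 7 to 1636, and the correlation of duplicate spots from 0.562 to 0.903. The number of cows limits the precision. Signal over background was not analysed here.

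The group means were fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, in 1 fit of the 10 cow means. The tests were the cyclic mean against 0, the pregnant mean against 0, the mean of both groups against 0, and pregnant minus cyclic, each two-sided, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Fixed lists (28, with 678 genes measured in all) were tested with camera at a preset correlation of 0.01, on the 8066 genes with a value in all 10 cows. The same lists were tested with an estimated correlation and with the rotation test fry, which asks whether a list's genes move 1 way and compares them with no other genes. Adjusted p of lists are over the 28 lists, and members were counted over all genes and adjusted over the list alone. Permutations of single values were exact. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

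The comparisons, the lists, the settings listed first in the last paragraph and the rule for named genes were fixed before the data were examined. The rule took, in each group, features with 1 symbol, adjusted p under 0.05 and the same sign in all 5 cows, up to 10 per direction. For the difference it took those past the threshold or, if none passed, the 5 with the smallest p. From each list past its test, or with at least 3 members past it, it took up to 4 members. Because the cow means gave only 6 named genes, the same rule was also applied to the planned fit of all 20 arrays with a dye term and cow as a random block. That use was chosen after the 6 had been seen. The consensus correlation within cows in that fit was 0.0977.

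The pipeline was tested on simulated data with 200 changed features per draw. On cow means, changes of 0.5, 1, 1.5 and 2 (log2) in 1 group were recovered in 64.0%, 96.9%, 99.8% and 99.9% of cases over 20 draws, with 8.15 false calls per draw. For the difference the shares were 30.3%, 85.4%, 97.4% and 99.5%. With all 20 arrays the shares in 1 group were 72.7%, 99.3%, 100% and 100% over 3 draws. Features were drawn independently with normal noise, without arrays of doubted direction or signal that followed the dye. The shares therefore do not tell how often changes of these sizes pass in the real data. A list lowered by 0.2 or 0.4 was called in 20 of 20 draws and in 0 of 20 without a change, with genes drawn independently of each other.

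Other settings fixed at that stage were centred, scaled or quantile-normalised arrays, arrays of 1 dye orientation, the 20-array fit, each group fitted alone, eBayes with trend and robust, filters on missing values and on the difference between dye swaps, a threshold of 0.01, the other list tests, and each cow left out in turn. Settings chosen after seeing the data were arrays turned or left out, pregnant cows 1 and 5 left out, and a running median over 101 neighbouring features subtracted from each array, some of these also in the 20-array fit.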

Results

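Endometrial gene expression was compared between caruncle and intercaruncular tissue in 5 cyclic and 5 pregnant cows. The measurements were log2 ratios of 13821 array features covering 8073 genes, on 2 dye-swapped arrays per cow. Between 26012 and 27641 of 27648 spots had a value on an array. Values are means ± SD over cows (n = 5), as deposited, and positive values are read as higher in caruncle. That direction is likely but not stated in the sources, and if it is wrong all signs turn together. The log base was taken as 2.

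The first comparison asked which genes differ between the 2 areas in cyclic cows. All 6 genes named by the rule were lower in caruncle. CDCA7, a nuclear protein of dividing cells, had a log ratio of -1.45 ± 0.17 (adjusted p = 0.0296). The tight-junction gene CLDN5 (-1.01 ± 0.48), the glutathione transferase GSTM3 (-0.99 ± 0.48), the aldo-keto reductase AKR1B1, which acts in prostaglandin synthesis (-0.69 ± 0.27), and the vesicle gene SYNGR2 (-0.59 ± 0.18) each had an adjusted p of 0.0340. The cytoskeletal adaptor SORBS2 was at -0.62 ± 0.20 (adjusted p = 0.0396). All 6 were below 0 in 5 of 5 cows, as the rule required, while a second feature of CDCA7 was at -0.19 ± 0.16.

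With limma on cow means, 10 features passed, 2 higher and 8 lower in caruncle, and 1335 (9.66%) had an unadjusted p under 0.05 against 691 by chance. The 4 other features had no symbol, with means of 1.05, 0.80, -0.93 and -0.54. The count was 0 without each of cyclic cows 1, 2, 3 and 4 and without pregnant cow 4, 115 without cyclic cow 5, 67 without pregnant cow 1, 19 without pregnant cow 2 and 3 without pregnant cow 3 (pregnant cows enter through the shared spread). It was 0 with eBayes trend and robust, 71 without 3 arrays of doubted direction or content (both of pregnant cow 1 and that of pregnant cow 5 with caruncle in Cy3), and 176 (39 higher, 137 lower, including all 10) in the 20-array fit.

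In the 20-array fit, 10 named genes were higher and 10 lower in caruncle of cyclic cows, CDCA7 and CLDN5 among the latter. That fit took 1 correlation within cows for all features (0.0977), while the 2 arrays of cyclic cows correlated across features at 0.0399 to 0.668. Where the arrays of a cow nearly repeat each other, it counts them almost as separate replicates. Its p may therefore be too small and its counts too large. Pleiotrophin (PTN), a heparin-binding growth factor, was at 1.85 ± 0.62 and neuropeptide Y (NPY) at 1.76 ± 1.36. The secreted Wnt inhibitors SFRP4 and SFRP1 were at 1.04 ± 0.98 and 0.94 ± 0.57, and the matrix protein gene SPON1 at 0.88 ± 0.45. The basement membrane collagen chains COL4A5 and COL4A6 were at 0.75 ± 0.57 and 0.74 ± 0.57, and AMPH, CCDC8 and C18H19orf48 were at 0.84 ± 0.64, 0.70 ± 0.37 and 0.67 ± 0.52. Lower in caruncle were the calcium-binding protein gene S100G (-1.44 ± 0.54), the homeobox gene MSX1 (-1.33 ± 0.75), the alanine transaminase GPT2 (-1.32 ± 0.67), the tight-junction gene CLDN1 (-1.24 ± 0.79), TSPAN1 (-1.09 ± 0.58), the fatty acid desaturase FADS2 (-1.06 ± 0.60), the transporter SLC16A11 (-1.05 ± 0.69) and LOC613966 (-1.37 ± 0.92). These 18 genes had the stated sign in 5 of 5 cyclic cows, as the rule required. Their adjusted p lay between 0.00182 for GPT2 and 0.0461 for SFRP1 in that fit, and between 0.0514 and 0.181 on cow means, where none passed. Second features of S100G (-0.02 ± 0.07) and MSX1 (-0.04 ± 0.09) stayed near 0.

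**Figure D1:**
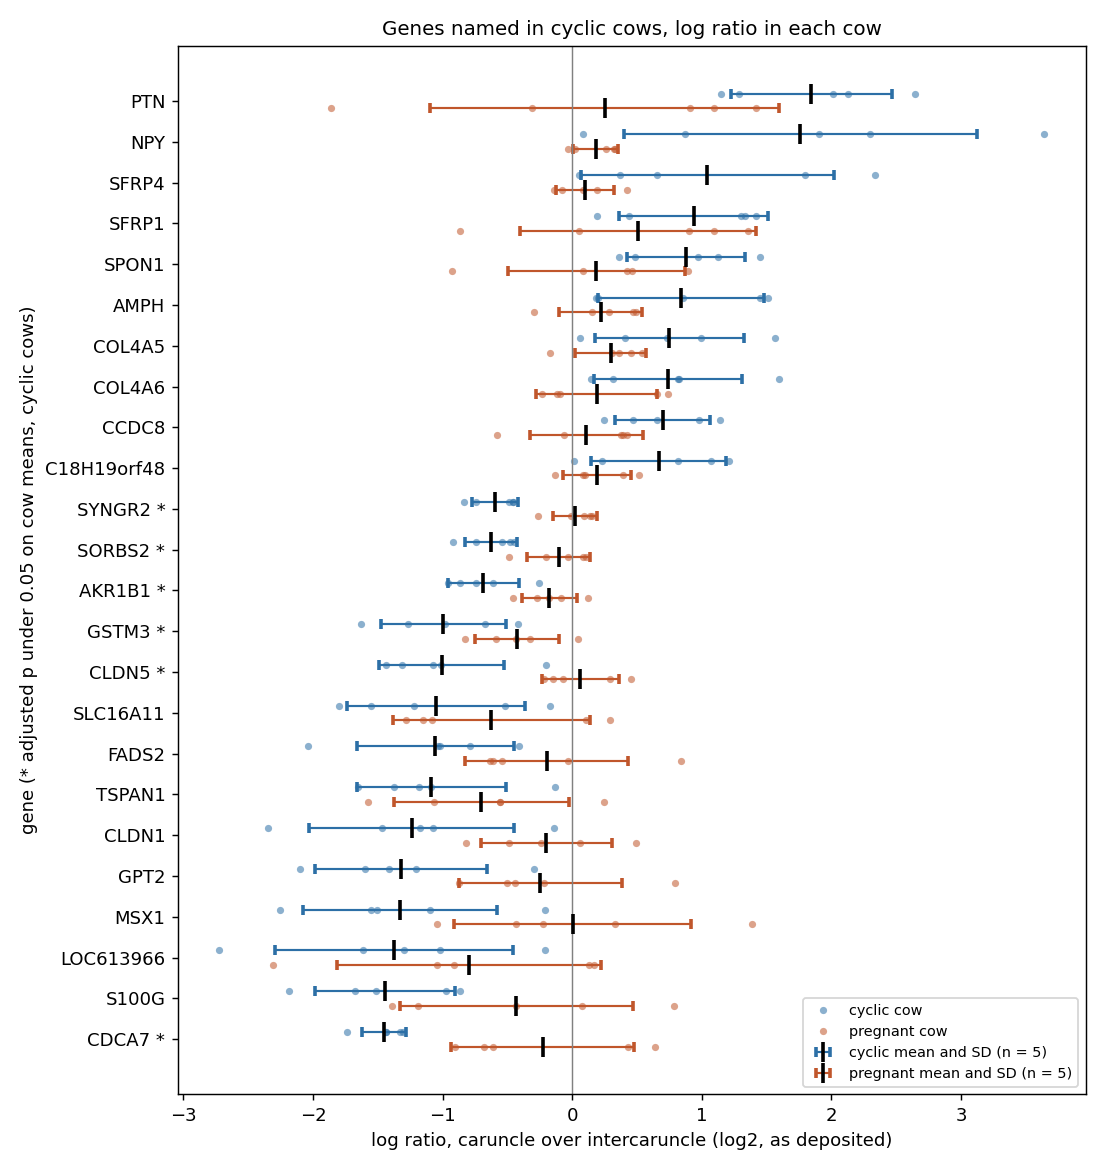
Log ratios (log2, as deposited, x axis) of 24 genes (y axis) in each of 5 cyclic and 5 pregnant cows, with black bars for group means and whiskers for SD; a star marks adjusted p under 0.05 on cow means in cyclic cows. The cyclic mean of CDCA7 was -1.45 and that of PTN 1.85, against pregnant means of -0.23 and 0.25.

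Epithelial marker genes were lower in caruncle of cyclic cows as a group, with 20 of 21 members below 0 and a list median of -0.46 (camera adjusted p = 2.4e-15, and adjusted p = 0.378 with an estimated correlation). The direction of this result follows the reading of the ratio, which no list settled. Occludin (OCLN, -0.77 ± 0.34), the transcription factor KLF5 (-0.93 ± 0.60), E-cadherin (CDH1, -0.96 ± 0.61) and the membrane protease ST14 (-0.73 ± 0.21) were below 0 in 5 of 5 cows. OCLN alone was past the threshold over all 8066 genes of the list tests. It was not among the 10 features past the threshold over all 13821 features. Adjusted over the list alone, 15 members were past it, all lower. With fry the adjusted p was 0.0533.

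Collagen genes were above 0 in 19 of 21 cases (median 0.23, adjusted p = 2.3e-06, and adjusted p = 0.463 with an estimated correlation). COL4A5 and COL4A6 passed adjusted over the list alone and none over all genes, and COL5A3 and COL12A1 were at 0.35 ± 0.30 and 0.29 ± 0.28. Basement membrane genes were above 0 in 12 of 16 cases (median 0.13, adjusted p = 0.00112, and adjusted p = 0.463 with an estimated correlation). Of these the laminins LAMA4 (0.36 ± 0.17) and LAMB1 (0.45 ± 0.34) passed with the 2 collagen IV chains, adjusted over the list alone, and none over all genes. Stromal fibroblast genes were above 0 in 11 of 18 cases (median 0.15, adjusted p = 0.0125, and adjusted p = 0.463 with an estimated correlation). PTN and the nuclear receptor NR2F2 (0.57 ± 0.21) were higher adjusted over the list alone, none over all genes, and THY1 and SNAI2 were at 0.47 ± 0.51 and 0.35 ± 0.33. The stromal call ended without cyclic cow 1 (adjusted p = 0.147) and without the array of pregnant cow 1 with caruncle in Cy5 (0.0920). Cytosolic ribosomal protein genes were above 0 in 47 of 55 cases (median 0.10, adjusted p = 0.000235, and adjusted p = 0.533 with an estimated correlation). RPL14 (0.31 ± 0.16), RPL13A (0.33 ± 0.29), RPL7A (0.29 ± 0.27) and RPL38 (0.30 ± 0.28) had the smallest p in that list, and 0 members passed over all genes or adjusted over the list alone with limma (6 higher and 1 lower at unadjusted p under 0.05). With fry these 4 lists each had an adjusted p of 0.283. Other patterns of signs over the 5 cyclic cows gave up to 10 lists past camera, against the 5 described.

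Transporter genes did not pass as a list (camera adjusted p = 0.123), but 7 of 26 were lower in caruncle adjusted over the list alone, 0 of them over all genes with limma (9 lower at unadjusted p under 0.05). Among them were S100G (mean of its features -0.73 ± 0.28), the glutamate transporter SLC1A1 (-0.91 ± 0.80), the water channel AQP1 (-0.52 ± 0.25) and the carbonic anhydrase CA2 (-0.58 ± 0.40). In the list of HOX, MSX and WNT genes (adjusted p = 0.606), MSX1 (mean of its features -0.68 ± 0.38), PAX8 (-0.57 ± 0.26) and HOXB2 (-0.76 ± 0.54) were lower, and SFRP4 and SFRP1 higher, adjusted over the list alone. Over all genes 0 of these passed with limma (3 higher and 4 lower at unadjusted p under 0.05). In the proliferation list (adjusted p = 0.233), the ribonucleotide reductase RRM1 (-0.55 ± 0.17), geminin (GMNN, -0.89 ± 0.62) and cyclin B1 (CCNB1, -0.84 ± 0.40) were lower adjusted over the list alone, and 0 over all genes with limma (3 lower at unadjusted p under 0.05). Gland product genes were split, 6 above and 6 below 0 (median -0.05, adjusted p = 0.454), with SPP1 at 0.65 ± 0.41, MUC1 at -0.50 ± 0.26, SCARA5 at -0.52 ± 0.29 and SERPINA14 at -0.55 ± 0.65. The 23 lists not past camera had adjusted p from 0.0508 (IGF system) to 0.802.

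The second comparison asked the same question in pregnant cows. No single gene passed over all genes, and the 5 lists below passed with camera at the preset correlation only. Stromal fibroblast genes were above 0 in 14 of 18 cases (median 0.17, adjusted p = 0.00034, and adjusted p = 0.502 with an estimated correlation). The transcription factor SNAI2 (0.62 ± 0.26), the matrix protein gene SPARC (0.61 ± 0.42) and vimentin (VIM, 0.49 ± 0.34) were higher adjusted over the list alone, each above 0 in 5 of 5 cows, and FBLN1 was at 0.31 ± 0.22. With the arrays of pregnant cows 1 and 5 with caruncle in Cy3 turned, SNAI2, SPARC and VIM were at 0.74 ± 0.50, 0.72 ± 0.86 and 0.38 ± 0.35. Smooth muscle genes were above 0 in 17 of 19 cases (median 0.15, adjusted p = 0.000269, and adjusted p = 0.502 with an estimated correlation), with TPM2 at 0.26 ± 0.07, CNN1 at 0.51 ± 0.58, TAGLN at 0.53 ± 0.61 and PDLIM3 at 0.17 ± 0.12. Collagen genes were above 0 in 19 of 21 cases (median 0.17, adjusted p = 0.000269, and adjusted p = 0.674 with an estimated correlation), with COL6A3 at 0.68 ± 0.54, COL3A1 at 0.53 ± 0.35, COL1A2 at 0.40 ± 0.36 and COL1A1 at 0.52 ± 0.56.

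Basement membrane genes were above 0 in 10 of 16 cases in pregnant cows (median 0.19, adjusted p = 0.0455, and adjusted p = 0.674 with an estimated correlation). SPARC and LAMA4 (0.30 ± 0.08) were higher adjusted over the list alone, and NID1 and LAMB1 were at 0.19 ± 0.10 and 0.21 ± 0.11. Epithelial genes were below 0 in 16 of 21 cases (median -0.15, adjusted p = 0.00801, and adjusted p = 0.674 with an estimated correlation), with CLDN3 at -0.35 ± 0.34, EHF at -0.38 ± 0.26, KRT18 at -0.31 ± 0.40 and ST14 at -0.27 ± 0.61. In the smooth muscle, collagen and epithelial lists 0 members passed with limma over all genes or adjusted over the list alone (3 and 4 higher and 2 lower at unadjusted p under 0.05). The epithelial call ended without pregnant cow 2 (adjusted p = 0.0823), 3 (0.262) or 4 (0.344), and the basement membrane call without pregnant cow 1 (0.144), 2 (0.120) or 3 (0.211) or without cyclic cow 2 (0.0510) or 4 (0.0560). All 5 calls ended without the array of pregnant cow 1 with caruncle in Cy5 (adjusted p from 0.350 to 0.948). The value of cow 1 was then its doubted array with caruncle in Cy3 alone. All 5 calls also ended with all 5 arrays with caruncle in Cy3 turned (0.516 to 0.669), and 0 lists passed with fry (lowest adjusted p = 0.359). Without the 3 doubted arrays the adjusted p was 0.0665 for collagens and for smooth muscle and 0.494 for basement membrane, and other sign patterns gave up to 10 lists past camera. The basement membrane call also ended with the arrays of pregnant cows 1 and 5 with caruncle in Cy3 turned (0.131) and without both cows (0.0981).

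With limma, 0 features passed in pregnant cows on cow means (746 at unadjusted p under 0.05, against 691 by chance, lowest adjusted p = 0.842) and 0 in the 20-array fit (664 at unadjusted p under 0.05). The median SD between cows was 0.230, against 0.198 in cyclic cows. The count was 21 (11 higher, 10 lower) with the arrays of pregnant cows 1 and 5 with caruncle in Cy3 turned, and 0 with that of cow 1 alone turned. Among the 21 were SFRP1 (0.96 ± 0.29) and SLC16A11 (-1.09 ± 0.39), each with an adjusted p of 0.0488. As deposited, their pregnant means were 0.51 ± 0.91 and -0.63 ± 0.76.

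Interferon-stimulated genes, which interferon tau of the conceptus induces in the uterus, did not pass as a list in pregnant cows. Of 42 genes 16 were above 0 (median -0.07, adjusted p = 0.174), and in cyclic cows 23 were (median 0.01, adjusted p = 0.802). The list medians of pregnant cows 1 to 5 were -0.70, -0.08, 0.25, 0.35 and -0.09, so the direction in pregnant cows rested largely on cow 1. A single array, that of pregnant cow 1 with caruncle in Cy5, held ISG15 at -4.91, MX1 at -4.49 and RSAD2 at -4.98. The dye-swapped array of the same cow had them at -0.21, 0.38 and 0.23. Epithelial genes had medians above 0 on the arrays of pregnant cows 1 and 5 with caruncle in Cy3, and below 0 on the 18 other arrays.

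**Figure D2:**
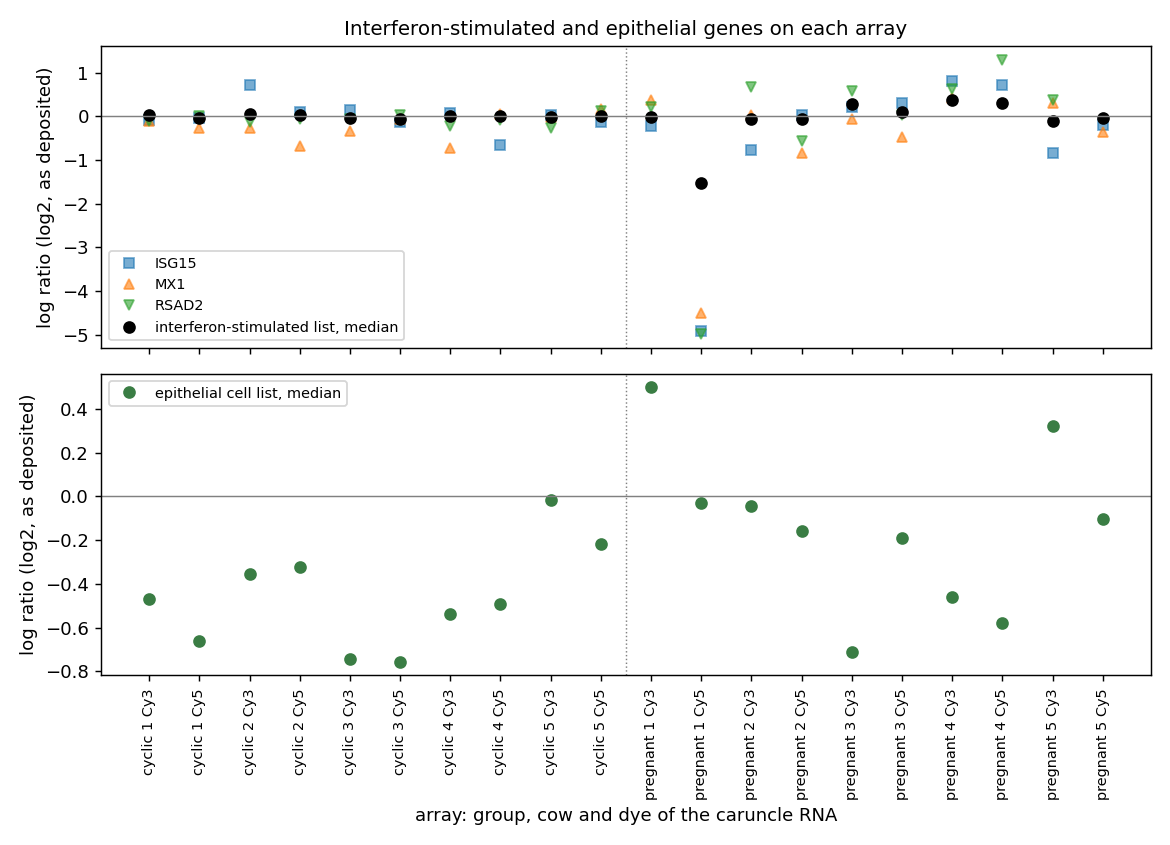
Log ratios (log2, as deposited, y axes) on each of 20 arrays (x axis, by group, cow and dye of the caruncle RNA): ISG15, MX1, RSAD2 and the median of the interferon-stimulated list in the upper panel, and the median of the epithelial list in the lower panel. The interferon median was -1.53 on the array of pregnant cow 1 with caruncle in Cy5, and the epithelial median was above 0 on the arrays of pregnant cows 1 and 5 with caruncle in Cy3.

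**Figure D3:**
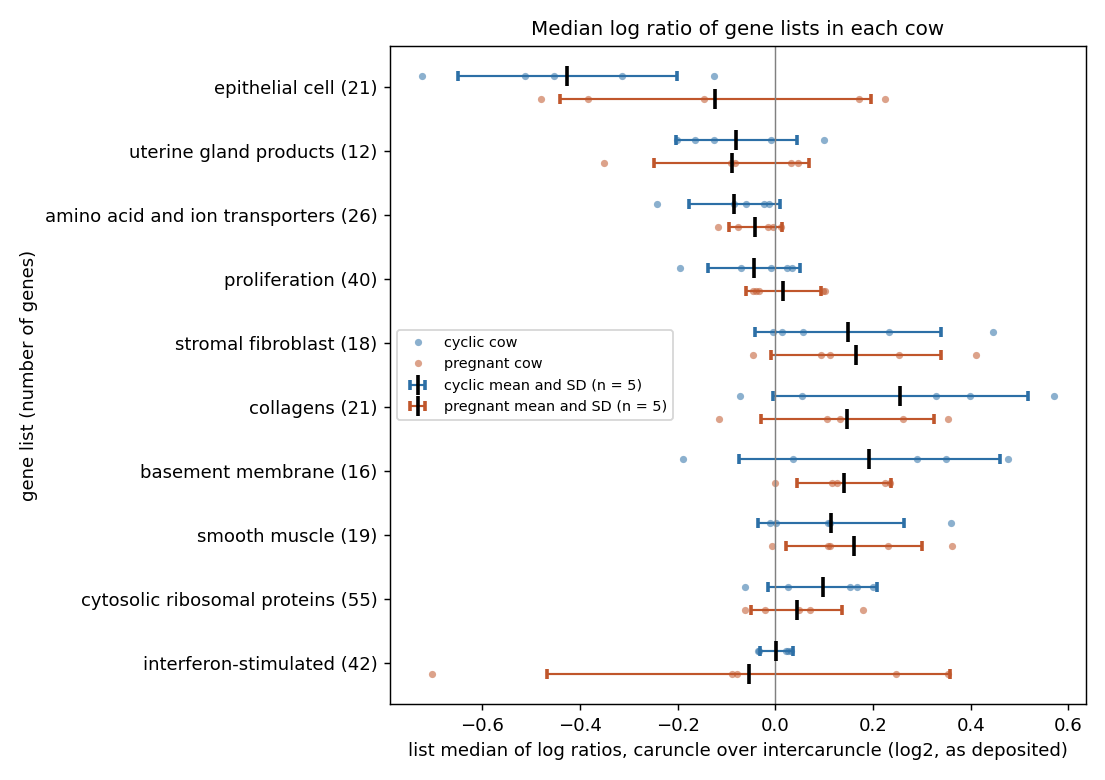
List median of log ratios (log2, as deposited, x axis) for 10 gene lists (y axis, number of genes in brackets) in each of 5 cyclic and 5 pregnant cows, with black bars for group means and whiskers for SD. The epithelial medians averaged -0.43 in cyclic and -0.12 in pregnant cows, and those of collagens 0.26 and 0.15.

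The third comparison asked whether the area difference itself differed between pregnant and cyclic cows. Epithelial genes were less low in caruncle in pregnant cows: pregnant minus cyclic was above 0 in 18 of 21 members (median 0.39, camera adjusted p = 1.3e-06, and adjusted p = 0.877 with an estimated correlation). Over cows, the list medians averaged -0.43 ± 0.22 in cyclic and -0.12 ± 0.32 in pregnant cows, a difference that an exact two-sided permutation did not place past the threshold (p = 0.143). The adjusted p was 0.875 with fry and 0.0660 without pregnant cows 1 and 5. No member passed over all genes or adjusted over the list alone with limma (0 past, 7 higher at unadjusted p under 0.05).

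The 5 genes with the smallest p for pregnant minus cyclic did not pass (adjusted p = 0.681 each). They were CLDN5 (difference 1.07, pregnant 0.06 ± 0.30), SYNGR2 (0.62, pregnant 0.02 ± 0.17), the Hedgehog ligand IHH (1.22, from -0.98 ± 0.61 to 0.23 ± 0.30), the TEAD family transcription factor TEAD2 (0.70, from -0.16 ± 0.19 to 0.54 ± 0.25) and the myosin MYO5B (0.54, from -0.43 ± 0.18 to 0.12 ± 0.12). IHH, TEAD2 and MYO5B were above 0 in 5 of 5 pregnant cows as deposited. For TEAD2 this came mainly from 1 dye orientation. With caruncle in Cy5 it was at 1.38, 0.41, 0.84, 0.83 and 1.61 in pregnant cows 1 to 5. With caruncle in Cy3 it was at 0.16, 0.0033, 0.45, -0.14 and -0.18. IHH was at only 0.03, 0.04 and 0.01 in pregnant cows 2, 3 and 4. The 2 arrays of a cow had opposite signs for IHH in pregnant cows 1, 2, 3 and 4, and for MYO5B in cows 2, 3 and 5. With the arrays of pregnant cows 1 and 5 with caruncle in Cy3 turned, the pregnant means were -0.13 ± 0.36 for IHH, 0.54 ± 0.27 for TEAD2, -0.07 ± 0.24 for MYO5B, -0.14 ± 0.33 for CLDN5 and -0.10 ± 0.18 for SYNGR2. With limma 0 features passed for the difference (682 at unadjusted p under 0.05, against 691 by chance), and 0 in the 20-array fit (701). The count was 5 with all 5 pregnant arrays with caruncle in Cy3 turned.

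As deposited, the genes named in cyclic cows had mean log ratios nearer 0 in pregnant cows. Such genes were chosen for passing in cyclic cows, so means nearer 0 in other cows were partly built in, whatever their state. PTN was at 0.25 ± 1.35, NPY at 0.18 ± 0.17, CDCA7 at -0.23 ± 0.71, S100G at -0.43 ± 0.90 and GPT2 at -0.25 ± 0.63 in pregnant cows. With the arrays of pregnant cows 1 and 5 with caruncle in Cy3 turned, PTN was at 0.85 ± 0.44, NPY at 0.68 ± 0.71, CDCA7 at -0.53 ± 0.39, S100G at -0.90 ± 0.39 and GPT2 at -0.64 ± 0.28, and SFRP1 and SLC16A11 were at 0.96 ± 0.29 and -1.09 ± 0.39, against 0.94 and -1.05 in cyclic cows. Without both cows (n = 3), PTN was at 1.14 ± 0.26 and CDCA7 at -0.73 ± 0.15, the latter with a limma adjusted p of 0.0405. Of the 20 genes the rule took from the 20-array fit, 18 had the sign of their cyclic mean in the mean of the 5 pregnant cows and 20 in that of cows 2 to 4. The exceptions as deposited, CLDN5 and MSX1, were at -0.14 ± 0.33 and -0.46 ± 0.39 with the 2 arrays turned. The genes had been chosen on their cyclic values, and the 2 arrays were doubted because they ran against the cyclic arrays. Pregnant values closer to the cyclic ones, with the arrays turned or the cows left out, were thus built in by the choice. The difference passed for none of these genes. Averaged over both groups, 0 features passed with limma on cow means (1357 at unadjusted p under 0.05, lowest adjusted p = 0.0759) and 53 in the 20-array fit (13 higher, 40 lower). The count on cow means was 62 without pregnant cow 1, 38 without cyclic cow 5, 1 without pregnant cow 5, 172 with the array of pregnant cow 1 with caruncle in Cy3 turned, and 141 without the 3 doubted arrays.

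Cyclic and pregnant mean log ratios correlated across features with Pearson's r = 0.266 and Spearman's rho = 0.190, as a description only, since features are not independent replicates. The mean log ratios of single pregnant cows correlated with the cyclic means at -0.175, 0.297, 0.353, 0.338 and -0.225 for cows 1 to 5. The correlation was 0.103, 0.149 and 0.147 without pregnant cows 3, 2 and 4, and 0.382 and 0.388 without cows 1 and 5. It was 0.493 over pregnant cows 2 to 4 and 0.505 with the arrays of cows 1 and 5 with caruncle in Cy3 turned. Those cows and arrays were singled out because they ran against the cyclic values, so both rises were built in by the choice. As deposited 0 features were called in both groups, which the pregnant count of 0 fixed in advance. With the 2 arrays turned, 7 of the 21 features called in pregnant cows were also called in cyclic cows, and without cows 1 and 5 it was 4 of 9, all with the same sign in both groups. The choice of those arrays and cows raises this overlap and the shared signs too, so they are no separate evidence that the groups agree.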

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

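Tests on turned or left-out arrays, those of the 5 pregnant arrays, of the 20 genes, of single arrays of cows 1 and 5 and of interferon genes below -1, and the permutations of list medians were chosen after the results had been seen, while the running-median tests, the sign patterns and splits, and the test of the list with 2 arrays turned were written before their results.

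Of 124 groups of values examined for a sample far from the others, 7 (5.65%) held one, 2 cyclic and 5 pregnant, and chance gives about 5%, or 1 in 20. On the array labelled pregnant cow 1 with caruncle in Cy5 the interferon-stimulated genes had a median of -1.53, against -0.11 to 0.37 on the other pregnant arrays. Cholesterol and fatty acid synthesis genes had a median of 0.0809 in cyclic cow 4, against -0.23 to -0.14 in the other cyclic cows. Complement genes had a median of 0.31 in pregnant cow 3, against -0.09 to 0.02 in the other pregnant cows. Missing spots numbered 1636 on the array of cyclic cow 5 with caruncle in Cy3, against 7 to 109 on the other cyclic arrays, and 904 on that of pregnant cow 1 with caruncle in Cy3, against 7 to 266. The correlation of duplicate spots was 0.562 on the array of pregnant cow 3 with caruncle in Cy5, against 0.765 to 0.903. The correlation of neighbouring features was 0.750 on the array of pregnant cow 5 with caruncle in Cy5, against 0.143 to 0.433. The epithelial list differed between the groups by a test of the difference itself, with a camera adjusted p of 1.3e-06, which was 0.877 with an estimated correlation and 0.875 with fry.

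The interferon-stimulated genes RSAD2 (-4.98), ISG15 (-4.91), MX1 (-4.49) and MX2 (-3.46), antiviral genes that the embryo's interferon tau induces in the pregnant ruminant uterus, were among the lowest genes on the array labelled pregnant cow 1 with caruncle in Cy5, and 11 of its 25 lowest genes were in the list against 0.13 by chance. A signal that follows position in the number order of features is argued against, since the list median was -1.49 after the running median was subtracted. The layout of the slide was not used, so a local fault on the slide was not tested. An area difference in the cow itself is argued against too, since the dye-swapped array of the same cow had a median of -0.0041, with MX1 at 0.38. On that array 0 list genes lay below -1, against 23 here and at most 3 on any other array. RNA of another animal or state in 1 channel may account for these values but stays open, because no array compares the states directly.

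The dye-swapped arrays of the pregnant cows did not run together (correlations from -0.216 to 0.183), and tables argue against all 5 arrays with caruncle in Cy3 having been left unturned, since 3 of them correlated above 0.1 with the cyclic mean. They argue against position in the number order of features as the whole cause, since the median correlation was -0.0804 after the running median was subtracted. The correlation still went from -0.114 to 0.0177 in cow 4 and from -0.216 to -0.107 in cow 5 (cows 1 and 2 were at -0.118 and -0.0804). Position on the slide itself was not tested. An opposite area difference in cows 1 and 5 themselves is argued against as the sole cause. It would show on both arrays of a cow, whose correlations were -0.0844 in cow 1 and -0.216 in cow 5. Whether such a difference exists beside another cause stays open. Of their 4 arrays 2 had an epithelial median above 0, and the 2 others, at -0.03 and -0.10, lay within the SD of 0.38 between pregnant arrays. Tissues or sign exchanged on the arrays of pregnant cows 1 and 5 with caruncle in Cy3 stays a candidate explanation. Of 20 genes named in cyclic cows, 0 had the cyclic sign on the array of cow 1 and 5 on that of cow 5. That met a bound set after the results, and the 2 arrays had been doubted because they ran against the cyclic arrays. The count was thus largely built in, and a reversed area difference would give the same signs on these arrays. On the arrays with caruncle in Cy5, PTN was opposite in cow 1 too (-1.46) and CLDN1 in cow 5 (0.50). S100G had the cyclic sign in both cows (-0.09 and -0.55), as had CLDN1 in cow 1 (-0.36) and PTN in cow 5 (0.11). An exchange leaves the low correlations of cows 2 and 4 unexplained, and it was found and tested on the same arrays. A part of the signal that followed the dye passed the threshold with limma in 1076 features in pregnant cows and 0 in cyclic cows. Such a part lowers the correlation of the dye-swapped arrays of a cow, but it was not tested as the cause.

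The epithelial list was less low in caruncle in pregnant than in cyclic cows. The direction of the 2 doubted arrays stays open as a cause: camera at the preset correlation gave an adjusted p of 0.00766 with both turned (range over all alternatives 3.4e-09 to 0.877), which met a bound set beforehand against it, but that bound ignored the estimated correlation of 0.37 between the list's genes. Over cows the difference of list medians went from 0.30 to 0.14 with both turned (exact permutation p = 0.278), and without pregnant cows 1 and 5 it was 0.09 (camera adjusted p = 0.0660). Pregnancy may account for it and stays open too, since the exact permutation p over 252 splits was 0.143 as deposited. A first test had counted 3 of 5 pregnant cows within the cyclic range, which met its own bound against pregnancy, and the permutation replaced it after that result was seen, because overlapping ranges do not exclude a difference in means.

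In other sign patterns of the 5 cyclic cows (16 in all, the real one included) only 1, the real pattern with CDCA7, CLDN5 and 8 other features, gave as many as 10, and the highest other gave 0. In pregnant cows all 16 patterns gave at least the real 0, the highest other 3. For the lists, 9 of 16 patterns gave as many as the real 5 in cyclic cows and 6 of 16 in pregnant cows, each with a highest other of 10. With 16 patterns no share under 0.05 can be had. Over both groups (real 0, highest other 492) and for the difference (real 0, highest other 15) all 100 patterns or splits drawn gave as many, which a count of 0 fixes in advance, as in pregnant cows, so nothing follows about chance. For lists in the difference (real 1, highest other 13) 87 of 100 splits gave as many, so chance cannot be excluded there. A pattern with 492 features may reflect a structure of the samples, which was not identified, and patterns with 10 lists weaken each list call made with the preset correlation, the epithelial one included.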

How the results depend on the processing

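Alternatives that turned or left out arrays, left out pregnant cows 1 and 5 or subtracted a running median were chosen after seeing the data; the others were planned. For the 24 genes named in cyclic cows, 410 of 648 comparisons kept direction and side of the threshold, 189 newly passed and 49 no longer passed, and none reversed. On cow means, settings that changed only pregnant arrays could not reverse a cyclic mean. Leaving out 1 cyclic cow could not either, since the rule required 1 sign in all cyclic cows. Most of these genes had been chosen because they passed in the 20-array fit, so passing there was fixed by the choice. The 5 genes of the difference stayed short of the threshold in all 135. List calls held in 98 of 110 comparisons in cyclic cows, 77 of 110 in pregnant cows and 19 of 22 for the difference. The cyclic count (10) was 0 at a threshold of 0.01, 0 with eBayes trend and robust, 1 with each group fitted alone, 56 with scaled arrays, 94 with quantile normalisation, 68 with caruncle in Cy5 only and 0 in Cy3 only, 75 with the array of pregnant cow 1 with caruncle in Cy3 turned, 156 with that of cow 5 turned too, 102 with all 5 turned, 1 with that array of cow 1 left out, 71 without the 3 doubted arrays and 159 without pregnant cows 1 and 5. The 20-array fit gave 176, 340 without the doubted arrays, 241 with the running median and 303 with 2 arrays turned. On cow means, leaving out single cows gave 0 to 115. The pregnant count (0, limma, 746 at unadjusted p under 0.05) was 15 with caruncle in Cy5 only, 21 with 2 arrays turned, 366 with 5 turned, 9 without pregnant cows 1 and 5, and in the 20-array fit 2 without the doubted arrays and 108 with 2 turned. On cow means it was 0 without any single cow. Over both groups the count (0, 1357 at unadjusted p under 0.05) was 1 with scaled arrays, 89 with caruncle in Cy5 only, 1 in Cy3 only, 172 with 1 array turned, 499 with 2, 133 with 5, 33 without the array of pregnant cow 1 with caruncle in Cy3, 141 without the doubted arrays and 325 without pregnant cows 1 and 5. In the 20-array fit it was 53, 434 without the doubted arrays, 55 with the running median and 745 with 2 turned. On cow means it was 0 to 62 without single cows. The difference count (0, 682 at unadjusted p under 0.05) was 5 with 5 arrays turned and 0 without any single cow. Lists past the threshold in cyclic cows (5) were 0 with an estimated correlation, 1 with fry, 8 without the doubted arrays and 4 to 7 without single cows. In pregnant cows (5) they were 0 with an estimated correlation, 0 with fry, 8 with 2 arrays turned, 2 with 5 turned, 9 without the array of pregnant cow 1 with caruncle in Cy3, 3 without its other array, 8 without pregnant cows 1 and 5 and 3 to 9 without single cows. For the difference (1) they were 0 with an estimated correlation, 3 with 1 array turned, 5 with 2, 6 with 5, 4 without the array of pregnant cow 1 with caruncle in Cy3, 3 without its other array, 6 without the doubted arrays, 3 without pregnant cows 1 and 5, 5 with the running median and 1 to 6 without single cows. The correlation of cyclic and pregnant effects ranged from 0.0788 to 0.505, and from 0.103 to 0.388 without single cows. The cause was not tested. Signal over background was not analysed here, so its limit on weak features is unknown.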

Other observations

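The values in these paragraphs were singled out after they had been seen, and the test of the dye-aligned signal was chosen then, while the list tests had been fixed.

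Both PGR and OXTR, hormone receptor genes, had means of opposite sign in the 2 groups. The progesterone receptor PGR was at -0.24 ± 0.26 in cyclic cows and 0.32 ± 0.15 in pregnant cows (above 0 in 1 and 5 of 5), a difference of 0.56 that passed adjusted over the list alone (adjusted p = 0.0202) but not over all genes (0.648). The oxytocin receptor OXTR was at -0.39 ± 0.36 and 0.40 ± 0.64. With the arrays of pregnant cows 1 and 5 with caruncle in Cy3 turned, PGR and OXTR were at 0.41 ± 0.27 and 0.34 ± 0.54 in pregnant cows. The list of steroid and oxytocin receptors and partners had 10 of 17 genes above 0 for pregnant minus cyclic (median 0.09) and passed with fry (adjusted p = 0.00746) but not with camera (0.115, and adjusted p = 0.877 with an estimated correlation). In cyclic cows 13 of 17 were below 0 (fry adjusted p = 0.0122, camera 0.127, and adjusted p = 0.463 with an estimated correlation).

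Clusterin (CLU), a chaperone in the complement list, was lower in caruncle of cyclic cows (-0.89 ± 0.48, adjusted p over all genes 0.0413). Like OCLN, it was not among the 10 features past the threshold over all features. In pregnant cows CLU was at 0.01 ± 0.37, a difference of 0.90 past adjusted over the list alone (adjusted p = 0.0284) and not over all genes (0.648). In the same list the protease MASP2 went from 0.26 ± 0.23 to -0.21 ± 0.17 (adjusted p = 0.0372 over the list alone). With the same 2 arrays turned, CLU and MASP2 were at -0.12 ± 0.20 and -0.10 ± 0.28 in pregnant cows. The matrix protein tenascin C (TNC) was at 1.07 ± 0.99 in cyclic cows (above 0 in 4 of 5, adjusted p = 0.0329 over the list alone). The ribosomal protein gene RPS18 was at -0.15 ± 0.22 and 0.42 ± 0.17, and cathepsin K (CTSK), a collagen-degrading protease, at 0.01 ± 0.17 and 0.39 ± 0.20, the latter above 0 in 5 of 5 pregnant cows (adjusted p = 0.0262 over the list alone). Trophoblast genes had list medians of 0.0038 and -0.05 (adjusted p = 0.802 and 0.182).

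The part of the signal that followed the dye of the caruncle RNA passed the threshold with limma in 0 features in cyclic cows (551 at unadjusted p under 0.05) and in 1076 in pregnant cows (858 higher and 218 lower with caruncle in Cy5, 3490 at unadjusted p under 0.05). No other tool was run on it. Where both arrays of a cow had a value, this part equals the cow mean with the array with caruncle in Cy3 turned. The count of 366 in pregnant cows with all 5 such arrays turned rests on the same quantity. It was fitted there with the cyclic means as deposited, and is no separate result. The correlation of the dye-following part between neighbouring features was 0.269 and 0.495, against 0.0788 and 0.380 for the area difference itself.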
